A study of Zea mays with 8 samples.

How the data were processed

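Transcript levels were measured in the above-ground tissue of maize seedlings (Zea mays, B73 background) collected 11 days after planting, with an Affymetrix maize GeneChip that reads each transcript by a set of short probes, a probe set. The 8 arrays fall into 4 pools of wild-type seedlings and 4 pools of their DpDf siblings, with 12 plants in each pool. DpDf (duplicate-deficient) plants come from a translocation between chromosomes 5 and 6: per the labels, they carry an extra copy of most of the short arm of chromosome 5 and lack the outermost piece of the short arm of chromosome 6 on 1 of their homologues. Seedlings were progeny of self-pollinated DpDf plants and were sorted by a marker near the chromosome 5 break. The labels give 2 seed sources, each with 2 arrays per genotype.

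The deposited values are linear intensity values, 1 per probe set and array, already processed by the authors. The submitters' processing notes name MAS5, without a version and without its role. Any scaling target, and the genome build behind the probe annotation, is not given in the sources used here. Array medians and quartiles were nearly equal, so no further normalization was applied before taking log2. No pseudocount was needed. Detection calls are not given in the sources used here.

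Of 17734 probe sets, 113 array controls were left out of the comparisons. Gene names came from the platform annotation, updated by gene number through a RefSeq table of the assembly Zm-B73-REFERENCE-NAM-5.0. That table was used for names, chromosome and gene order, and none of its coordinates is given. Of the 17621 remaining probe sets, 1452 had 1 gene, 1 had several and was not named, and 16168 had none in that annotation. They covered 1108 genes, of which 1060 were placed on a chromosome. Probe sets with a mean log2 value under the 30th percentile (a linear value of 27.0) were left out, which kept 12335 probe sets and 919 named genes, 885 of them placed. A gene was represented by its probe set with the highest mean.

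Differences between DpDf and wild-type pools were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with genotype as the only term and Benjamini-Hochberg adjustment over all 12335 probe sets; the threshold was an adjusted p of 0.05. Intervals are 95% intervals of that fit. The duplicated segment was taken as the placed genes from the tip of the short arm of chromosome 5 to a limit near the centromere set before the data were examined, which held 51 tested genes. A further 4 genes around the centromere were put in neither set, and 44 genes stood for the long arm. Segment and list shifts were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation; fry was run on the lists. A gene's interval was compared with 0 and with log2(3/2), 0.58, the log2 ratio of 3 copies to 2. Calls inside and outside the segment were compared by Fisher's exact test. For per-array values, the median over genes of log2 value minus wild-type mean was tested by a two-sided exact permutation test over the 70 assignments of 8 arrays, whose smallest p is 0.0286. Differences between seed sources were tested as an interaction term. The planned limit for the deficient tip of chromosome 6 held 0 tested genes, and so did a narrower one; the values given come from a wider limit, also set before the data were examined, which held 3 genes.

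Gene list themes were chosen before the data were examined, except 5 (aquaporins, MADS-box genes, cytoskeleton, nitrogen assimilation and translation factors), which were added after the annotation had been seen. Because the annotation carries no descriptive gene names, the members of all lists were written out by symbol after the annotation was seen and before any comparison of the genotypes. Of 33 lists, 32 had at least 3 tested genes. The homeobox list was written with knowledge that the published study discusses such genes and is not independent evidence.

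Genes named in the text follow a rule set before the data were examined: the 10 largest rises and 10 largest falls past the threshold with the same direction in all 4 replicate pairs, the 6 segment genes with the smallest p, the 4 segment genes with the highest probe set signal, all tested genes of the chromosome 6 tip, and the 2 members with the smallest p in each list described that did not pass its test. Not every gene that meets the rule is named. A gene named outside this rule is said to be so.

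Wild-type and DpDf pools with the same replicate number come from the same sowing and seed source, per the labels. Their deviations from the group means correlated across probe sets at r = 0.36, 0.51, 0.56 and 0.33 for replicates 1 to 4, and each wild-type pool correlated best with the DpDf pool of its own number, so the numbers pair the samples. The planned fit has no block; the fit with replicate number as a block was run as an alternative. Other alternatives covered normalization, a pseudocount, the low-value filter, the variance model, seed source, the segment's limit, the treatment of several probe sets per gene, and leaving out each array. No array columns were identical. Pairwise correlations of log2 values ran from 0.980 to 0.995.

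The procedure was tested on simulated data for DpDf against wild type, with the real means and spreads of 12335 probe sets and 200 changed ones. It recovered 76.0% of changes of log2(3/2) and 94.0% of log2 changes of 1, and 3.95% of its calls were unchanged probe sets. The simulated noise was independent between probe sets and arrays and had no replicate pairs, so these rates may not hold for the real calls.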

Results

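Expression was profiled in 8 pools of 12 maize seedlings, 4 wild type and 4 DpDf. The comparison asks how an extra copy of most of the short arm of chromosome 5 alters transcript levels, both of the genes it carries and elsewhere in the genome. Values are log2 differences, DpDf minus wild type, with the standard error (SE) of the limma fit and n = 4 pools per genotype unless stated.

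Genes of the duplicated segment were higher in every DpDf pool. The median of the 51 segment genes, relative to their wild-type means, was 0.40, 0.45, 0.45 and 0.36 in DpDf replicates 1 to 4, against 0.060, -0.072, 0.023 and -0.0098 in the wild-type pools. The group means were 0.41 ± 0.045 (SD, n = 4) and 0.00043 ± 0.056 (SD, n = 4), and they differed with p = 0.0286 in a two-sided exact permutation test, the smallest p that 70 assignments allow. Genes of the long arm of chromosome 5 (44 genes) differed by -0.052 (exact permutation p = 0.0857) and genes of other chromosomes (786 genes) by -0.039 (exact permutation p = 0.0571). Adjusted over the 4 gene sets tested this way, the p for each set was 0.0857. With the replicate pairs kept together, the segment difference was also 0.41, and its p of 0.125 is the smallest that 16 exact sign flips allow.

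**Figure D1:**
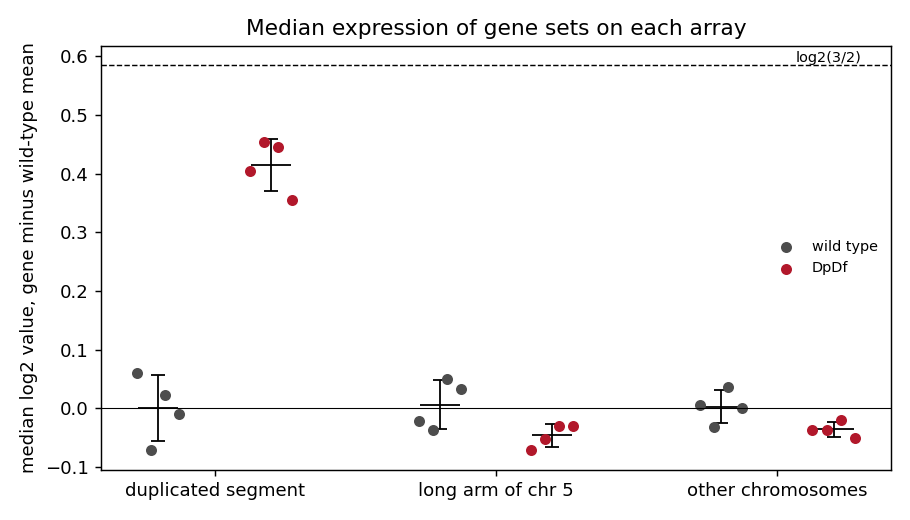
Median log2 value of each gene set on each array, after subtracting each gene's wild-type mean; points are pools, horizontal lines group means and bars SD (n = 4). Segment medians of the DpDf pools lie between 0.36 and 0.45, below the dashed line at log2(3/2), 0.58.

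Across the segment, 48 of 51 genes had a higher mean in DpDf. Their median log2 difference was 0.47, a 1.39-fold rise (95% bootstrap interval over genes 1.24 to 1.43), while the medians for the long arm and for other chromosomes were -0.027 and -0.041. The segment's shift passed limma's camera test (p = 3.32e-35 at the preset correlation, p = 0.000416 with an estimated correlation). RPL19, a ribosomal protein gene, was the segment's most proximal gene and was raised by 0.53 (SE 0.043, adjusted p = 0.000360 in limma). mbd109, a methyl-CpG-binding domain gene, rose by 0.68 (SE 0.063, adjusted p = 0.000686), sqs1, encoding squalene synthase, by 0.60 (SE 0.057, adjusted p = 0.000770) and crd101 by 0.47 (SE 0.055, adjusted p = 0.00139) in the limma fit.

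Rises above the copy ratio were measured for 3 segment genes. LOC542243 went from a log2 value of 3.57 ± 0.41 (SD, n = 4) in wild type to 7.12 ± 0.20 in DpDf, a difference of 3.55 (SE 0.20, limma adjusted p = 8.16e-05). Its wild-type level, a linear value of 11.9, lies below the filter value of 27.0, so background limits the size of this difference and its rank. Next to it in gene order, sbe1, which encodes a starch branching enzyme, rose by 1.05 (SE 0.076, limma adjusted p = 0.000228), and pht1 rose by 1.22 (SE 0.19, limma adjusted p = 0.00515). sig6, a sigma factor of the plastid RNA polymerase, and hk3, a histidine kinase of the cytokinin pathway, rose by 0.91 and 0.87, with intervals that hold log2(3/2); with the replicate block both intervals lay above it.

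Segment genes read by the brightest probe sets had smaller differences, and signals of different probe sets do not rank expression. TCTP, encoding the translationally controlled tumour protein, rose by 0.15 (SE 0.030, limma adjusted p = 0.0211), rpp3, an acidic ribosomal protein gene, by 0.16 (SE 0.032, limma adjusted p = 0.0177) and arf1 by 0.27 (SE 0.040, limma adjusted p = 0.00394). RPL10 differed by -0.013 (SE 0.048, limma adjusted p = 0.925), and its other probe set differed in direction. Across the 51 genes, which are not independent replicates, the difference fell with mean probe set signal (Spearman's rho = -0.39, permutation p = 0.0044). TCTP, rpp3 and RPL10 were read by probe sets that may be shared between transcripts, and signal was not separated from such sharing.

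Set against dosage, the intervals of 40 of the 51 segment genes lay above 0. For 27 genes the interval held log2(3/2) but not 0, for 10 it lay between the 2 values, and for 8 it held 0 but not log2(3/2). The interval held both values for 2 genes, lay above log2(3/2) for 3 (5 with the replicate block) and lay below 0 for 1. That gene is pglcat8 (-0.20, SE 0.069), named after its value was seen, and 1 of its other probe sets differed in direction. In all, 19 intervals lay below log2(3/2). Among the 44 long-arm genes, 2 intervals lay above 0, 7 below it, and 35 held it.

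In gene order along chromosome 5, the median was 0.47 over the first 40 measured genes, 0.044 over genes 41 to 80 and -0.012 over the last 19. In bins of 10, chosen after seeing the data, medians were 0.47, 0.51, 0.47, 0.22 and 0.33 over genes 1 to 50. RPL19 at position 51 was the last segment gene past the threshold. The bin of genes 51 to 60, which begins with it, had a median of -0.00036, and medians of the later bins ran from -0.079 to 0.011.

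**Figure D2:**
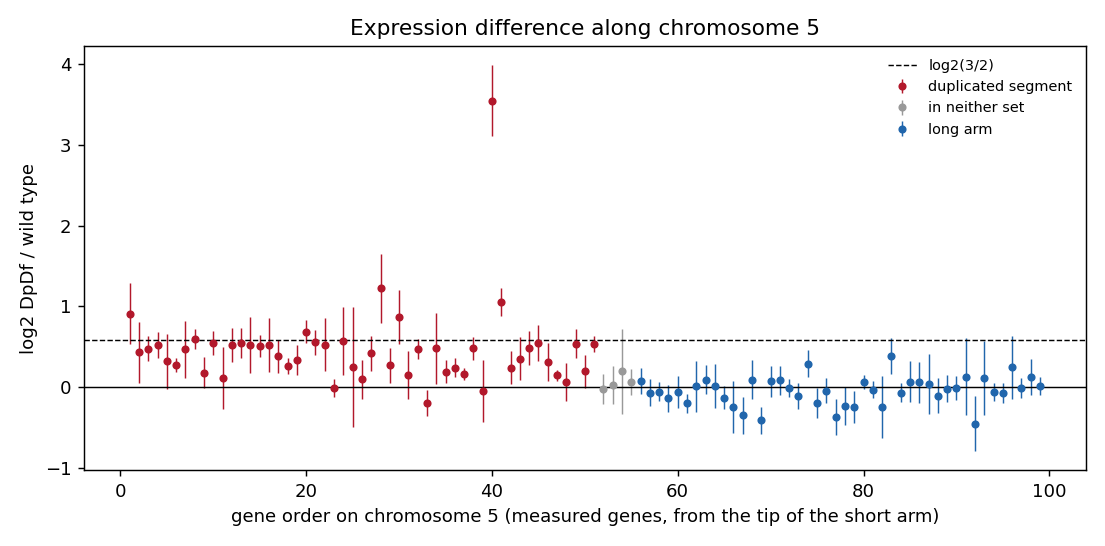
Log2 difference between DpDf and wild type for 99 measured genes of chromosome 5, in gene order from the tip of the short arm; points are limma estimates and bars 95% intervals (n = 4 pools per genotype). Most segment genes lie between 0 and the dashed line at log2(3/2) and values beyond position 51 scatter around 0.

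Over the whole array, 601 of 12335 probe sets passed the limma threshold, 497 of them higher in DpDf and 104 lower. Every one of them changed in the same direction in all 4 replicate pairs. The threshold itself favours such probe sets, so this is not separate support. Higher calls had a median of 0.53 and lower calls a median of -0.48; 13 higher calls reached a log2 difference of 1 and 7 lower calls a difference of -1. The largest values belonged to 2 probe sets of the same transcript, which carry no gene name (4.65, SE 0.29, limma adjusted p = 0.000120, and 4.37, SE 0.25, limma adjusted p = 8.16e-05). The former had a linear value of 16.3 in wild type, under the filter value of 27.0, so background limits the size of its rise. The largest falls among probe sets without a name were -1.34 (SE 0.097) and -1.20 (SE 0.20). With replicate number as a block, limma called 1253 probe sets, 840 higher and 413 lower, and 600 of the 601 were among them. A measure of RNA quality was taken from 5 control transcripts chosen after the control values were seen. Its 3' minus 5' log2 difference was 0.91 ± 0.13 (SD, n = 4) in wild type and 1.20 ± 0.23 in DpDf. It was higher in DpDf in all 4 pairs (exact permutation p = 0.0571), most of all in replicate 1 (0.81 against 1.52). Because of that choice, this p is not an independent test. With this 3' minus 5' measure as a covariate, an alternative chosen after seeing the data, 337 probe sets passed, 305 higher and 32 lower. The measure is partly confounded with genotype, so calls lost with it are not shown to come from RNA quality. Without that covariate, 389 passed when wild-type replicate 4 was left out, 43 of them lower. The lower calls also numbered 54 without wild-type replicate 3 and 66, 66, 62 and 65 without DpDf replicates 1 to 4.

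Among placed genes, higher calls concentrated in the duplicated segment. Of the 497 higher calls, 451 were probe sets without a placement and do not enter this comparison. Of its 51 genes, 28 were called higher and 0 lower, against 12 higher and 10 lower among 834 placed genes elsewhere (odds ratio for higher calls 81.6, 95% interval 35.3 to 200.2, Fisher's exact p = 1.15e-29). Genes measured on the same pools are not independent replicates, so that p and interval do not cover variation between pools. The odds ratio was 55.6 with the replicate block and 174 without wild-type replicate 4. With the replicate block, 36 segment genes were called higher, and 34 genes elsewhere were higher and 45 lower. The 22 genes called elsewhere became 7 with the 3' to 5' measure as a covariate. They numbered 7, 14, 13 and 12 without wild-type replicate 4, wild-type replicate 3, DpDf replicate 2 and DpDf replicate 4.

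The largest rises of named genes outside the segment were those of BMY1, gst42, sus2 and phytase1. BMY1, a beta-amylase gene, rose by 0.83 (SE 0.19, limma adjusted p = 0.0339) and sus2, a sucrose synthase gene, by 0.71 (SE 0.083, limma adjusted p = 0.00139). phytase1, encoding an enzyme that releases phosphate from phytate, rose by 0.71 (SE 0.098, limma adjusted p = 0.00308) and gst42, a glutathione S-transferase gene, by 0.72 (SE 0.17, limma adjusted p = 0.0460). In replicate 3 the log2 value of gst42 hardly differed, at 6.387 in wild type and 6.390 in DpDf. Falls were measured for hda106, a histone deacetylase gene (-0.68, SE 0.14), and TUBB2, a beta-tubulin gene (-0.66, SE 0.084). mha1, a plasma membrane proton pump gene, differed by -0.66 (SE 0.15) and mir3 (LOC100037824) by -0.53 (SE 0.088). cesa10, a cellulose synthase gene, fell by 0.50 (SE 0.076) and gpc4, a cytosolic glyceraldehyde-3-phosphate dehydrogenase gene on the long arm of chromosome 5, by 0.41 (SE 0.075). pk8-a fell by 0.32, LOC541901 by 0.32 and tbp1, encoding a TATA-binding protein, by 0.31. The limma adjusted p of these falls ran from 0.00196 for TUBB2 to 0.0498 for pk8-a. With the 3' to 5' covariate, 18 of the 34 called named genes missed the threshold with their direction kept, among them BMY1, gst42, hda106, mha1, mir3, cesa10, pk8-a, LOC541901 and tbp1. Over all called probe sets, the median was 0.56 with the covariate against 0.53 without it for higher calls, and -0.43 against -0.48 for lower calls.

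The chromosome 6 tip was represented by 3 genes. Narrower limits held 0 tested genes, so whether these 3 lie in the deficient piece and measure its loss is not known. Their per-array median differed by -0.097 between genotypes (exact permutation p = 0.0857), a call that quantile normalization changed (-0.11, exact permutation p = 0.0286). The latter p is not adjusted over the 4 gene sets. DpDf replicate 2 had the lowest value (-0.22, against -0.041, -0.037 and -0.12 in DpDf replicates 1, 3 and 4), and without it the difference was -0.059. In wild-type replicates 1 to 4 the values were -0.014, 0.022, 0.011 and -0.041, so DpDf was lower in each pair. fdx2, a ferredoxin gene, differed by -0.51 (SE 0.17, limma adjusted p = 0.163, and 0.00497 with the replicate block). frk2, a fructokinase gene, differed by -0.10 (SE 0.051, limma adjusted p = 0.358) and arpp1a, an acidic ribosomal protein gene, by 0.023 (SE 0.043, limma adjusted p = 0.837).

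None of the 32 gene lists passed limma's camera test: the smallest adjusted p was 0.116, 6 lists had an unadjusted p under 0.05, and with an estimated correlation the smallest adjusted p was 0.977. The smallest with the replicate block was 0.0768. fry found 0 lists moving one way on balance and 11 with changes in either direction, which does not compare a list with other genes.

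Among starch and sucrose genes, 3 of 21 were called higher and 0 lower, and 4 adjusted over the list alone (median 0.056, camera adjusted p = 0.116); sbe1, in the segment, and sus2 had the smallest p, and the replicate block gave 5 higher calls. Of 28 cell wall genes, 1 was called lower, cesa10, and 4 were lower adjusted over the list alone (median -0.077, camera adjusted p = 0.116). With the replicate block 2 cell wall genes were called higher and 4 lower. bk2, a gene needed for stalk strength, differed by -0.32 (limma adjusted p = 0.0521, and 0.0295 with the replicate block). Both lists passed with the 3' to 5' covariate (adjusted p = 0.0327 and 0.0283), but not at an estimated correlation (adjusted p = 0.961 for both). Of 29 cell cycle and replication genes, 0 were called and 23 had a lower mean in DpDf (median -0.084, camera adjusted p = 0.116); orc2, an origin recognition complex gene, differed by -0.37 and KIN9, a kinesin gene, by -0.45, and both passed with the replicate block (adjusted p = 0.0375 and 0.00939). All 9 mitochondrial respiration genes had a lower mean, with 0 called and 1 lower adjusted over the list alone (median -0.10, camera adjusted p = 0.116). In that list vdac2 differed by -0.48 and aox1 (LOC542074), an alternative oxidase gene, by -0.64 (limma adjusted p = 0.0205 and 0.0148 with the block). Another gene of that name, LOC542073 on the long arm of chromosome 5, named outside the rule, differed by -0.25 (limma adjusted p = 0.519). Photosystem and light-harvesting genes had a higher mean in 10 of 11 cases, with 0 called (median 0.11, camera adjusted p = 0.116), and psad1, a segment gene, and Cab-m7 differed by 0.47 (adjusted p = 0.00466 with the block) and 0.11. With the block, psad1 and 1 photosystem gene outside the segment were called. Without wild-type replicate 2, the photosystem and cell cycle lists passed (adjusted p = 0.0157 and 0.00703), and without DpDf replicate 1 the cell cycle and cell wall lists did (adjusted p = 0.0482 for both). At an estimated correlation these 4 values were lost as well (adjusted p = 0.895 without wild-type replicate 2 and 0.956 without DpDf replicate 1).

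Called genes of further lists lay partly or wholly in the segment. In the ribosomal protein list 3 of 19 genes were called higher, all of them in the segment, led by RPL19 and RPS10 (0.51, SE 0.062). Chromatin regulators had 4 of 52 called higher, all in the segment, and 1 lower; mbd109 and crd101 had the smallest p. Of the 52, 36 had a lower mean in DpDf (median -0.096), and without segment genes the unadjusted camera p was 0.0156 (adjusted p = 0.117). The replicate block gave 5 higher calls and 1 lower. Of 26 heat shock and chaperone genes, 3 were called higher: pdi4, encoding a protein disulfide isomerase, in the segment (0.55, SE 0.10), hsp26 on chromosome 1 (0.68, SE 0.14) and 1 more segment gene. With the replicate block, 5 genes of this list were called higher and 2 lower, and adjusted over the list alone 4 were higher and 1 lower. Cytokinin genes had 2 of 17 called higher, hk3 and the response regulator RR6 (0.47, SE 0.086). The cytoskeleton list held 1 higher call, tub4 in the segment (0.26, SE 0.045), and 1 lower, TUBB2, among 15 genes (1 and 2 with the block, and 1 and 2 adjusted over the list alone). Of 13 translation factors 1 was called, tif4A2 in the segment (0.24, SE 0.055), and tif1 differed by 0.17 (adjusted p = 0.0442 with the replicate block). Camera adjusted p for these 6 lists ran from 0.232 to 0.819.

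For the 13 homeobox genes, 0 passed the limma threshold, 0 adjusted over the list alone, and 10 had a lower mean in DpDf (camera adjusted p = 0.541). ocl4, expressed in outer cell layers, differed by -0.31 (SE 0.11) and rld1, a leaf polarity gene, by -0.33 (SE 0.15). With the replicate block, 5 of them were lower past the threshold: ocl4 (adjusted p = 0.0259), rld1 (0.0370) and, named after their values were seen, rld2 (0.0307) and the knotted-like genes kn1 (0.0387) and lg3 (0.0492), which differed by -0.29, -0.29 and -0.53 in limma. The leaf polarity and growth regulator list had 1 of 15 genes called, GRF13 (0.32, SE 0.074), and rs2 differed by -0.15 (camera adjusted p = 0.948; its median, -0.031, was negative while the test pointed up).

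The remaining lists had few or no calls. Oxidative stress and detoxification had 1 of 39 genes called, gst42, and apx, an ascorbate peroxidase gene, differed by -0.29 (adjusted p = 0.0492 with the replicate block in limma). Aquaporins had 0 of 24 called, and 1 higher and 3 lower with the block, with pip2d at 0.29 and pip2-5 at -0.26 (adjusted p = 0.0109 and 0.0345 with the replicate block in limma). The C4 mesophyll list (6 genes) and the bundle sheath list (4 genes) had 0 calls, with ppt1 at -0.19 and mdh6 at 0.23 (limma adjusted p = 0.0489 with the block) in the former and rbcS at 0.12 and me3 at 0.18 in the latter. Markers of other tissues gave 1 call, ohp2 of the seed list, itself in the segment (0.54, SE 0.066), where gz27 differed by -0.10. The pollen list (maf1, 0.24, and prf5, -0.053), the root and iron list (ys1, -0.23, and IDI2, 0.094) and the epidermis list (fae1, -0.068, and gl8, 0.091) had 0. Histones (his1a, -0.12, and his1 in the segment, 0.18), auxin (abp1, 0.14, and nitrilase1, -0.20), gibberellin (eks1, -0.24, and an1, 0.079), abscisic acid and dehydrins (a4Lea, -0.15, and dhn1, 0.47), and jasmonate and ethylene (opr1, 0.63, and hpl1, 0.26) had 0 calls. So did pathogenesis-related genes (pr5, 0.40, and cpi2, 0.24), benzoxazinoid synthesis (glu1, 0.24, and glu2, 0.17), flavonoids (a2, -0.18, and pl, 0.11), lignin (cncr1, 0.13, and pal3, -0.11), MADS-box genes (m6, 0.58, limma adjusted p = 0.00715 with the block, and m20, -0.23) and nitrogen assimilation (NIR, -0.12, and gln1, 0.095). Adjusted over the list alone, abp1 of the auxin list and rbcS of the bundle sheath list were higher past the threshold, and gst42 was not. Other probe sets of his1 and cpi2 differed in direction. Camera adjusted p over these 19 lists ran from 0.495 to 0.973.

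Between the 2 seed sources, the DpDf effect differed for 0 of 12335 probe sets in limma's interaction test, with 247 at an unadjusted p under 0.05, where chance alone gives about 617, and a smallest adjusted p of 1.00. With the replicate block, an alternative added after seeing the data that leaves 2 residual degrees of freedom, 0 passed and 510 had an unadjusted p under 0.05 (smallest adjusted p = 0.989). The segment median was 0.36 in the source of replicates 1 and 3 and 0.45 in that of replicates 2 and 4, each from 2 pools per genotype.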

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

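The tests of array scaling on the share of higher calls, of shared probes and of other groupings of the arrays were set before their results were seen; the other tests in this part were chosen after.

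The median rise of the segment genes was less than the ratio of 3 copies to 2. Array scaling was argued against as the whole cause on these arrays. Relative to genes of other chromosomes the segment median was 0.51, against 0.47 without that correction. Its 95% bootstrap interval of 0.36 to 0.56 ends below log2(3/2), 0.58. A part played by scaling stays open. The further medians and intervals in this paragraph are also relative to genes of other chromosomes, whose median was -0.041. The bootstrap intervals in this paragraph resampled genes and held the 8 arrays fixed, so they leave out variation between pools and do not settle the shortfall. Probe sets shared between transcripts were argued against as the whole cause on these arrays, since the 39 genes read by probe sets without a suffix had a median of 0.52 (0.42 to 0.56). The 12 genes read by probe sets with a suffix had 0.21 (0.16 to 0.46), so a part played by shared probes stays open. Saturation of bright probe sets stays open and may account for part of the shortfall. The 26 dimmer genes had a median of 0.56 (0.46 to 0.59) and the 25 brighter ones 0.31 (0.23 to 0.51). The interval of the dimmer genes only just holds log2(3/2). Without the correction for other chromosomes it would end below that value. TCTP, rpp3 and RPL10, among the brightest genes, were read by probe sets with a suffix, so saturation and shared probes are not told apart. Partial compensation of the extra copy, the biological explanation the design offers, stays open and was not tested.

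Higher calls outnumbered lower ones, 497 to 104. A scaling shift toward higher values was argued against, since genes outside chromosome 5 had a median of -0.041, the opposite direction. Centring the arrays on those genes took the share of higher calls from 82.7% to 89.7%. With a median of that sign the centring could hardly lower the share, so the rise is not separate support. The share of higher calls among placed genes predicts 510 (370 to 675) among the 11277 unplaced probe sets, and 451 were found. Anything that acts alike on named and unnamed probe sets would give this match, so it does not tell whether the unplaced higher calls lie in the segment, which stays open.

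The intervals of LOC542243, sbe1 and pht1 lay above the copy ratio, and with the replicate block those of sig6 and hk3 did too. If a short shared stretch of another haplotype were the cause, they would lie close together. A stretch that covers much of the segment need not bring them together, so their span cannot test it. The former 3 span 13 positions in gene order, and 0.157 of random draws of 3 segment genes span as little. All 5 span 40 positions, and 0.710 of random draws of 5 span as little, so no single short stretch holds them all. LOC542243 and sbe1 are neighbours at positions 40 and 41, and pht1 and hk3 lie at 28 and 30. The total span cannot detect a stretch that holds only some of these genes, so a shared stretch stays open. Other causes, such as gene-specific regulation, were not tested.

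The real grouping of the arrays was set against the other splits. Only the real one of 35 splits gave as many as 601 calls, and the highest other gave 10. Since the replicate numbers pair the samples, the comparison that counts is with the splits that part every pair; these are 8 with the real one, too few for a share under 0.05, and the others gave 0 calls. For the segment shift 1 of 35 splits was as large (0.51, highest other 0.29, and 0.25 among those that part every pair), and for segment genes called 1 of 35 (28, highest other 0). For gene lists, 0 passed in the real split, so all 35 splits give as many by construction and the count tests nothing. Most other splits passed a list or more, also among those that part every pair, so a list's pass at the preset correlation is weak evidence here. The highest other split passed 8 lists (5 among those that part every pair). The cause was not tested.

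A pool stood far from the other 3 of its genotype for 8 of 178 groups of values, and chance alone puts about 5% of groups beyond this limit. The gap as a share of the group's range was 0.934 for BMY1 in DpDf replicate 2, 0.915 for mha1 in DpDf replicate 3, 0.830 for rpp3 in DpDf replicate 2, 0.879 for Cab-m7 in DpDf replicate 3 and 0.964 for rbcS in DpDf replicate 1. It was 0.846 for hpl1 in wild-type replicate 2, 0.880 for pr5 in wild-type replicate 1 and 0.887 for m20 in wild-type replicate 1.

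Among the 5286 probe sets left out for low values, limma without the filter called 13 higher and 5 lower in DpDf.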

How the results depend on the processing

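Over the alternatives, 240 of 268 values of the main results stayed the same by a rule that depended on the kind of value. A tested value had to keep its direction and side of the threshold. A count had to stay within a ratio of 1.5 of the main count. The median of the first chromosome 5 bin had to keep its sign and move by less than the SD of its within-pair differences. Of 1510 values for named genes, 1366 kept direction and side of the threshold, 108 lost the call, 28 gained it and 8 changed sign. The camera shift of the segment and the enrichment of higher calls in it kept direction and side under every alternative run; the segment median ran from 0.40 to 0.48 and the odds ratio from 79.7 to 174 with each array left out. Segment genes called higher fell from 28 to 20 with the 3' minus 5' covariate and without wild-type replicate 4. Signal over background limits the low values: LOC542243 in wild type lies under the filter value. Tip limits narrower than the one reported held 0 genes and gave no value.

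Pairing by replicate block gave 1253 calls (840 higher, 413 lower) and 79 genes called outside the segment; the per-array segment difference kept its value, 0.41, with an exact p of 0.125, the smallest the sign flips allow. Seed source as a block gave 184 lower calls. At an adjusted p of 0.10, 231 were lower and 47 genes were called outside the segment. The 3' minus 5' covariate, added after seeing the data, gave 337 calls (305 higher, 32 lower), 7 genes called outside the segment and 2 lists. That covariate leaves fewer residual degrees of freedom and is partly confounded with genotype, so calls lost with it are not shown to come from RNA quality. Quantile normalization brought the chromosome 6 tip past the threshold (-0.11), and the 50th percentile filter, which leaves fewer genes, put the first chromosome 5 bin at 0.40; the cause of the former was not tested. The block also brought 15 named genes past the threshold, and 3 further homeobox genes, all given in the report with the list counts it moved. It changed the call of no other named gene and brought no gene list past its test.

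With each array left out, calls ran from 389 to 643, lower calls from 43 to 153, genes called outside the segment from 7 to 27 and lists from 0 to 2.

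Sign changes were among values that passed no threshold, and their cause was not tested. RPL10 was 0.0073 after median centring and 0.019 with the covariate, where me3 was -0.18 and gl8 -0.024; with each array left out they ran from -0.047 to 0.014, -0.021 to 0.33 and -0.014 to 0.15. The list test turned direction, with these medians, for abscisic acid after median centring (0.061) and the 50th percentile filter (0.038), and under that filter for leaf polarity (-0.037), cytokinin (-0.074), jasmonate (-0.098) and MADS-box genes (-0.056). Flavonoids turned (0.075) without a filter, with either block and without segment genes, jasmonate (-0.051) with all probe sets averaged and gibberellin (-0.0047) without segment genes. With the covariate it turned for chromatin (-0.0037), lignin (-0.090), auxin (-0.041), epidermis (-0.056), pollen (-0.012) and root (-0.028). With each array left out, medians of lists that turned ran from -0.056 to 0.0084 (leaf polarity), -0.041 to -0.014 (histones), -0.035 to 0.14 (flavonoids), -0.089 to 0.00011 (lignin), -0.095 to 0.0046 (auxin), -0.080 to 0.023 (gibberellin), -0.059 to 0.10 (abscisic acid), -0.084 to 0.028 (jasmonate), -0.070 to 0.037 (pathogenesis), -0.052 to 0.063 (epidermis), -0.045 to 0.024 (pollen), -0.0019 to 0.10 (root) and -0.11 to 0.14 (MADS-box).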

Other observations

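The array's control probe sets, which the comparisons left out, were examined only at the end. The 5' probe sets had a lower mean in DpDf for actin (-0.36), ef1a (-0.32), cyclophilin (-0.48), gapdh (-0.15) and ubiquitin (-0.29), while the 3' probe sets differed by -0.074, -0.072, -0.053, 0.020 and 0.025. None of these 5' probe sets passed the threshold among the controls (limma adjusted p from 0.259 to 0.691). By array, the 3' minus 5' difference was 0.81, 1.07, 0.79 and 0.97 in wild-type replicates 1 to 4 and 1.52, 1.20, 0.98 and 1.09 in DpDf replicates 1 to 4. With it as a covariate the segment median was 0.44, and 304 of the 601 calls were made in both fits. The 104 lower calls all kept a negative value, with a median of -0.43 in place of -0.48.

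A single control probe set of 113, for a middle part of gapdh, passed limma's threshold among the controls (AFFX-Zm-gapdh-M_s_at, -0.45, SE 0.062, adjusted p = 0.00219), and 13 had an unadjusted p under 0.05. The fall of gpc4, another probe set for a glyceraldehyde-3-phosphate dehydrogenase, was -0.41, while the 3' gapdh control differed by 0.020.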
